A study of Homo sapiens with 5 samples.

How the data were processed

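RNA sequencing of human coronary artery endothelial cells was analysed, with 2 libraries of cells transfected with a non-targeting siRNA (siCon) and 3 of cells transfected with an siRNA against JCAD (siJCAD). The labels call the samples biological replicates without saying whether they came from separate donors or days, so p-values measure only the spread between these 5 samples. The submitters left out siCon replicate 3, which aligned poorly, per the labels' protocols; it was not analysed here.

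Per the series' design text and the submitters' processing notes, libraries were made with the Illumina TruSeq V2 kit from poly-A RNA, a kit that does not mark strand, and sequenced as single reads of 100 nt. Per the same sources, reads were trimmed with Trimmomatic 0.32, aligned to GRCh38.p2 with STAR 2.4.2a and counted per gene with HTSeq 0.6.1 on GENCODE 23. The authors normalized the counts with DESeq2 1.10.1 and also ran Cufflinks 2.0.2, per the design text. The strand and overlap settings of the counting are not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart. Besides overlaps named at their gene, THBS1 shares bases with FSIP1, ANGPT2 with MCPH1, COL4A1 with COL4A2, MYH11 with NDE1, NOS3 with ATG9B and TYMS with ENOSF1, each on the other strand. The first deposited table holds raw counts for 24957 gene symbols, as whole numbers. The second table holds a normalized signal that the authors made by dividing each count by 1 size factor per library (0.995, 0.929, 0.941, 0.989 and 1.18 for siCon 1, siCon 2 and siJCAD 1 to 3), which DESeq2's median-of-ratios method gave again from the counts. Gene biotypes and identifiers other than symbols were not used from the tables. The number of columns belonging to other samples was 0.

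The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the raw counts, two-sided, with TMM factors (0.948 and 0.950 for siCon, 1.03 to 1.04 for siJCAD), the group as the only term, and Benjamini-Hochberg adjustment over the genes tested. The function filterByExpr, with its minimum count of 10, kept 14688 of 24957 genes and left out 10269. A gene was called at an adjusted p below 0.05. Standard errors are the unshrunk fitted log2 coefficient divided by the square root of F. The printed log2 fold changes are shrunk by a small prior count, which matters for scarce genes. The 95% intervals lie around the printed values and use the residual degrees of freedom (3) plus the prior ones (median 6.62). The biological coefficient of variation was 5.43%. Between libraries of a group the chi-square of counts per degree of freedom over genes was 2.96 to 8.73, above the value of 1 that sampling noise alone gives, so no library was taken for a copy of another; across groups it was 125 to 159. Reads carry no molecular identifiers, so intervals cover counting error and the spread between these libraries only.

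Before the data were examined, the groups, the tests, the alternatives, 22 genes (the targeted gene and others of endothelial biology) and 28 gene lists (592 genes, of which 545 were tested) were fixed. The rule for named genes was also fixed then: those 22 genes, the 10 largest rises and falls among called genes with a mean of at least 2 CPM, non-overlapping groups and a symbol that is not clone-based, and for each list the 2 members of smallest p, or 4 where the list was called or at least 4 members passed. The rule named 131 genes, 127 of which passed the test, and in 126 of these all siJCAD libraries lay beyond both siCon libraries. JAG1, VEGFC, TEK, ICAM2, the overlapping neighbours PI4KA, FAS and NUF2, members named without a value, and the gene families of the closing section with their members were chosen after their values were seen. Lists with at least 5 tested members (26 of 28) were compared with all other genes by camera of limma 3.58.1 on log2 CPM with a prior count of 2, at a preset inter-gene correlation of 0.01, with adjustment over the lists. It called 10 lists lower and 2 higher and left 14 uncalled. With the correlation estimated per list, 0 lists passed after adjustment (smallest adjusted p = 0.442) and 1, inflammatory activation, passed unadjusted (p = 0.0493). By fry, 21 lists passed in a direction and 25 for change in either direction. Genes may belong to more than 1 list (35 do).

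For sequence and positions, symbols were matched to GENCODE 44 on GRCh38, the same build as the counts: 13526 of the tested genes (92.1%) matched 1 gene, 769 of them through an older symbol, and 12715 had an annotated 3′ UTR in the canonical transcript. The word search (Python 3.11.15, numpy 2.4.6, pandas 2.3.3) regressed log2 fold change on the presence of each 7-base word found in at least 50 genes, with UTR length, base content and mean expression as covariates, and compared t with the strongest of 100 permutations of the residuals over genes. Genes are not independent replicates, so these t values rank words and test no difference between cultures. KIAA1462 was left out of that search.

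The tests were tested on simulated data, negative binomial counts at the means, library sizes and dispersions of the real ones, in which 200 genes were given known changes. Of the changed genes that passed the filter, 47 to 49 at each change, edgeR recovered 79.2% at a log2 change of -1, 68.1% at -0.5, 54.2% at 0.5 and 85.7% at 1. It tested 14377 genes and made 14 false calls (9.21% of its calls), a larger share than the threshold of 0.05 sets. Only 200 genes were changed here, whereas 63.04% of tested genes were called in the real data. The recovery and false-call rates therefore need not hold for the real comparison. Of 200 unshifted lists of 20 genes, 3% had a camera p below 0.05. These genes were drawn independently, so this rate does not cover lists whose genes vary together. Among the called lists the estimated correlation ran from 0.0452 (G1 and S phase) to 0.664 (interferon). A word given a shift of -0.3 in permuted values over 12713 genes ranked 1 of the words searched.

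Alternatives fixed in advance were DESeq2 1.42.0, limma-trend on the deposited normalized values with a pseudocount of 1, glmTreat of edgeR against a log2 change of 0.5, DESeq2 or upper-quartile factors in edgeR, no filter on low counts, at least 10 counts in every sample, each library left out in turn, the replicate number as a block, libraries thinned to the smallest total, and other set tests. For lists, ranges of adjusted p over alternatives leave out fry, which tests against no change and not against other genes. Settings that leave out carriers of the word or its core were added after the data were seen. Some genes that the rule names, and 1 of the lists, are not reported here.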

Results

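The experiment asked what happens to the transcriptome of human coronary artery endothelial cells, primary cells that line the arteries of the heart, when JCAD is depleted. JCAD, listed in the deposited tables under its older symbol KIAA1462, encodes a protein of endothelial cell junctions and lies at a locus associated with coronary artery disease. Cells at 80% confluence were transfected for 48 h with 100 nM of a small interfering RNA (siRNA) against JCAD, or with a non-targeting siRNA. Polyadenylated RNA was sequenced from 3 samples given the JCAD siRNA (siJCAD 1, 2 and 3) and from 2 given the non-targeting siRNA (siCon 1 and 2). The libraries held 21907077 (siCon 1), 20361838 (siCon 2), 18933397 (siJCAD 1), 20077283 (siJCAD 2) and 23904081 (siJCAD 3) counts assigned to genes. At these depths 1 count stood for 0.0418 to 0.0528 CPM (counts scaled to a library total of 1e+06) before composition scaling. The first principal component of log2 CPM held 86.6% of the variance and separated the siCon from the siJCAD libraries. Pearson correlations of log2 CPM, taken across genes, which are not independent replicates, lay between 0.994 and 0.995 within groups and between 0.951 and 0.954 across them. Values below are means ± SD of TMM-scaled CPM over 2 siCon and 3 siJCAD libraries, and log2 fold changes are siJCAD against siCon, ± SE.

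The targeted transcript fell in all 3 siJCAD libraries. KIAA1462 (JCAD in current annotation; GRCh38 chromosome 10, 30012803 to 30115494, minus strand, protein coding) had 4230 and 3836 counts in siCon 1 and 2, and 573, 617 and 720 counts in siJCAD 1, 2 and 3. Its level went from 201 ± 3.84 to 29.4 ± 0.325 CPM, a log2 fold change of -2.78 ± 0.048 (95% interval -2.88 to -2.67; edgeR adjusted p = 2.5e-10). The transcript was thus 6.85-fold lower.

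Depletion was accompanied by widespread differences. THBS1, the matricellular protein thrombospondin-1 and among the 10 most abundant transcripts of the siCon cells, fell from 9559 ± 259 to 938 ± 34.7 CPM, a log2 fold change of -3.35 ± 0.053. CCL2, a monocyte chemoattractant, fell from 265 ± 23.6 to 7.74 ± 1.78 CPM. HMOX1, the haem-degrading enzyme haem oxygenase-1, rose from 140.3 ± 1.93 to 1242 ± 74.8 CPM, and LCP1, an actin-bundling protein best known from leukocytes, rose from 0.598 ± 0.0407 to 36.3 ± 10.9 CPM. Of 14688 genes tested with edgeR, 9260 (63.04%) differed at an adjusted p below 0.05, 4568 higher and 4692 lower in siJCAD. Over 2-fold differences were found for 877 higher and 1511 lower genes, over 4-fold differences for 214 and 421, and over 8-fold differences for 65 and 133. Conversely, 4486 called genes (48.4%) differed by less than 1.5-fold. With a test against a log2 change of 0.5 in place of 0 (glmTreat), 1426 genes were higher and 2231 lower, so that 39.0% of calls were higher in place of 49.3%. The siCon and siJCAD libraries did not overlap for 76.0% of the genes tested, where chance gives 20%.

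**Figure D1:**
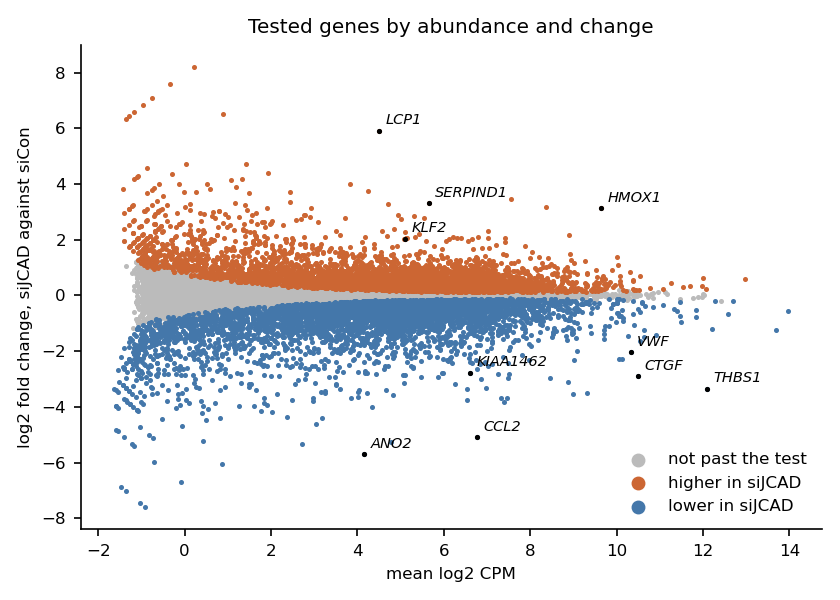
Each point is a tested gene, with its mean log2 CPM on the horizontal axis and its log2 fold change of siJCAD against siCon on the vertical axis; orange points were higher, blue points lower and grey points not past the test (edgeR, adjusted p below 0.05), and black points are labelled genes. Differences were found among scarce and abundant transcripts, from LCP1, which rose from 0.598 to 36.3 CPM, to THBS1, which fell from 9559 to 938 CPM.

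Among genes with a mean of at least 2 CPM and non-overlapping groups, the largest falls included secreted and surface proteins of the endothelium. The log2 fold change was -5.69 ± 0.17 for ANO2, a calcium-activated chloride channel, -5.32 ± 0.28 for PRND, -5.27 ± 0.096 for TNFSF10, the death ligand TRAIL, -5.08 ± 0.12 for CCL2, -4.63 ± 0.15 for FILIP1 and -4.40 ± 0.13 for SLC7A14. It was -4.37 ± 0.18 for SELE, the endothelial receptor for rolling leukocytes, -4.17 ± 0.27 for the ephrin receptor EPHA7, -4.13 ± 0.21 for the membrane-bound chemokine CX3CL1 and -4.01 ± 0.11 for the gap junction protein GJA4. The largest rises were those of LCP1 (5.92 ± 0.37), ATP6V0D2, a subunit of the vacuolar proton pump (4.72 ± 0.33), the folate-binding protein FOLR3 (4.39 ± 0.26), the fatty acid elongase ELOVL7 (4.19 ± 0.38) and the glycosyltransferase GALNT12 (3.99 ± 0.13). They were followed by the tight junction protein CGN (3.90 ± 0.30), the anchoring protein AKAP6 (3.76 ± 0.16), the apoptosis regulator BCL2A1 (3.71 ± 0.21), the Frizzled ligand NDP (3.67 ± 0.43) and the protease inhibitor SERPINB2 (3.48 ± 0.11). The edgeR adjusted p of these 20 genes ran from 2.8e-10 for TNFSF10 to 4.5e-05 for NDP. NDP, CGN, ELOVL7, FOLR3 and ATP6V0D2 had 2 to 10 counts in each siCon library, so their folds rest on few control counts.

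Genes fixed for their role in endothelial biology included targets and components of YAP/TAZ signalling. The YAP/TAZ targets CTGF (CCN2 in current annotation; chromosome 6, 131948176 to 131951372) and CYR61 (CCN1; chromosome 1, 85580761 to 85584589), both secreted matricellular proteins, had log2 fold changes of -2.91 ± 0.051 and -1.34 ± 0.052, and a further target, ANKRD1, one of -1.10 ± 0.062. The transcripts of the coactivators themselves did not pass the test: YAP1 had a log2 fold change of -0.07 (95% interval -0.34 to 0.19) and WWTR1, which encodes TAZ, one of 0.05 (-0.09 to 0.18). Without siJCAD 3, YAP1 passed at -0.22 (adjusted p = 0.0144). It also passed at -0.22 with the replicate number as a block (0.00603, with a range of 0.00603 to 1.00 over its alternatives). In that block siJCAD 3 does not inform the group difference, so the 2 settings are not separate evidence. The kinase LATS2, which restrains YAP and TAZ, had a log2 fold change of 0.60 ± 0.045.

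Other genes of the same fixed set moved in both directions. The vasoconstrictor peptide EDN1 had a log2 fold change of -2.96 ± 0.071, the adhesion receptors VCAM1 and ICAM1 ones of -2.75 ± 0.0997 and -0.84 ± 0.047, and VWF, the von Willebrand factor, one of -2.04 ± 0.065. The vascular cadherin CDH5 had one of -1.22 ± 0.046, the Tie2 ligand ANGPT2 one of -0.80 ± 0.048 and the anticoagulant receptor THBD one of -0.33 ± 0.063. F3, the tissue factor that starts coagulation, had 2.19 CPM in siCon and 2.13 CPM in siJCAD, which did not pass (log2 fold change -0.04, 95% interval -0.47 to 0.39). Higher were KLF2, the flow-responsive transcription factor (2.04 ± 0.083, from 11.96 ± 0.422 to 49.2 ± 3.32 CPM), the cell cycle inhibitor CDKN1A (0.91 ± 0.049) and the GTPase RHOA (0.40 ± 0.045). NOS3, the endothelial nitric oxide synthase, was higher by 0.37 ± 0.14 (edgeR adjusted p = 0.0402). It was the only 1 of 127 called genes named by the fixed rule whose groups overlapped. Its call was lost without siCon 1 (adjusted p = 0.134), siCon 2 (0.125), siJCAD 1 (0.1004) or siJCAD 2 (0.122), with a range of 8.2e-24 to 1.00 over its alternatives.

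**Figure D2:**
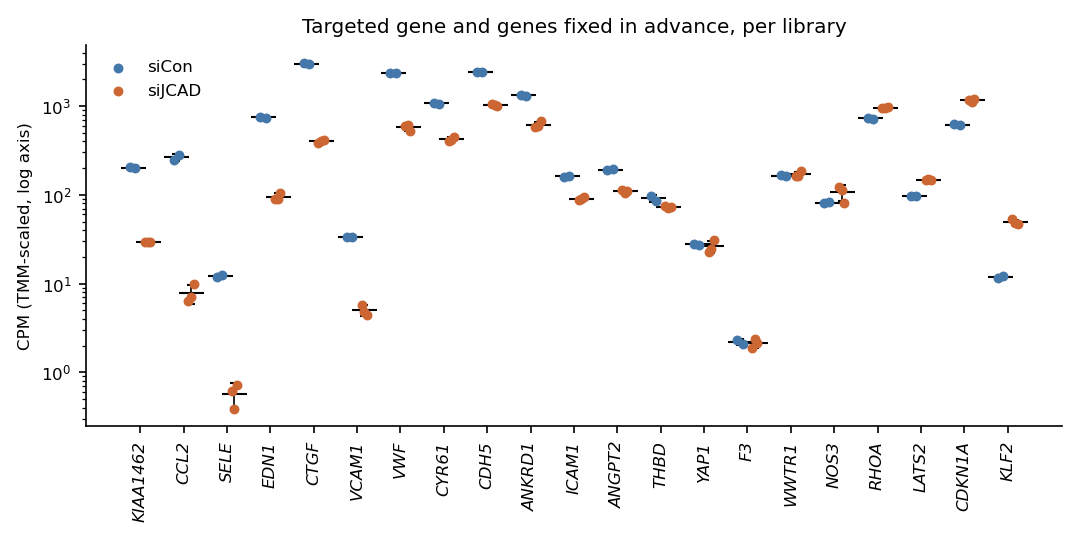
TMM-scaled CPM on a log axis of KIAA1462 and other genes fixed in advance, in order of log2 fold change; blue points are the 2 siCon and orange points the 3 siJCAD libraries, black marks are means and error bars SD. KIAA1462 has a mean of 201 CPM in siCon and 29.4 CPM in siJCAD, and NOS3, at 81.8 and 106 CPM, shows overlapping groups.

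Genes that were lower shared a sequence in their 3′ untranslated regions (UTRs). This search was not among the comparisons fixed before the data were examined. Each of 16211 words of 7 bases was tested, in the annotated 3′ UTRs of 12713 genes other than KIAA1462, for a difference in log2 fold change between genes with and without it, adjusted for UTR length, base content and expression. The strongest negative word was GGAAATG, carried by 2746 genes (21.6%), with an adjusted log2 difference of -0.38 ± 0.021 (t = -18.0), where the strongest negative t in 100 permutations was -5.21. The next was GAAATGA (t = -14.1), the same word shifted by 1 base. The median log2 fold change was -0.28 for 924 genes with the joined word GGAAATGA, of which 54.0% were lower, and -0.18 for 1822 genes with the leading word alone. It was -0.04 for 1213 genes with the shifted word alone and 0.06 for 2068 genes with only the 6-base core that these words share. It was 0.07 for 6686 genes without these words or their core, of which 27.5% were lower. Of the carriers of GGAAATG, 482 were lower by over 2-fold, where 191 were expected from genes of like UTR length that lack it. The adjusted difference was -0.34, -0.34 and -0.36 in siJCAD 1, 2 and 3 against the siCon mean, and -0.0059 between siCon 2 and siCon 1. CTGF, CYR61, ANKRD1, CDH5, YAP1, WWTR1, CCL2, CX3CL1, PRND, FILIP1, SLC7A14, EPHA7 and KIAA1462 itself carry the leading word in their 3′ UTR. THBS1, VCAM1, ICAM1, SELE, EDN1, VWF, ANGPT2, ANO2, TNFSF10 and GJA4 lack it, as do 68.5% of the 4290 lower genes with a searched UTR. Of these named genes, ANO2 carries the shifted word, and THBS1 and VCAM1 only the 6-base core.

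**Figure D3:**
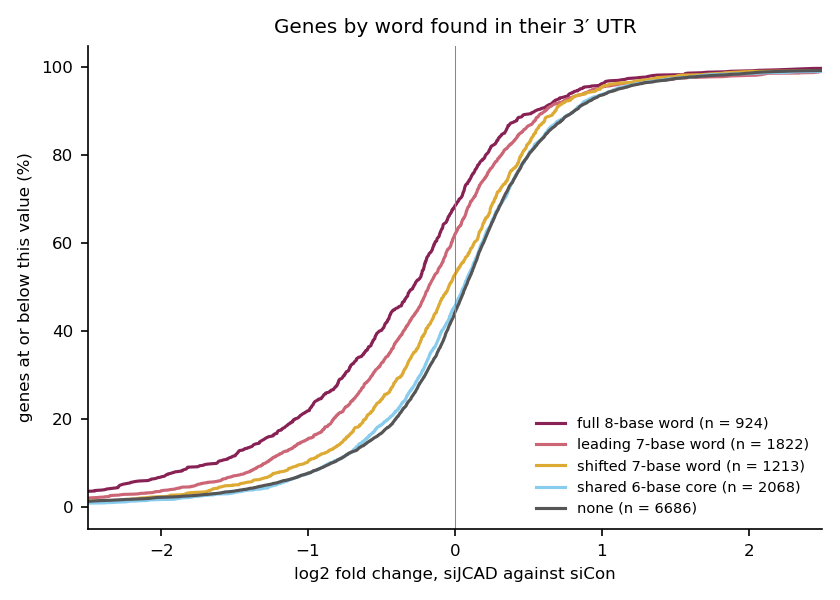
Cumulative percent of genes against log2 fold change of siJCAD against siCon, by the word in their annotated 3′ UTR: the full 8-base word GGAAATGA, the leading word GGAAATG alone, the shifted word GAAATGA alone, the shared 6-base core alone, or none. The curve of the 924 genes with the full word lies farthest to the left, with a median of -0.28, and that of the 6686 genes with none has a median of 0.07.

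Arterial and angiogenic genes were lower as groups. Of 15 tested Notch pathway and arterial identity genes, 2 rose and 13 fell (also adjusted over the list alone), with a median log2 fold change of -1.72. GJA4 and GJA5, arterial gap junction proteins, had values of -4.01 ± 0.11 and -3.82 ± 0.072, the arterial ephrin EFNB2 one of -2.81 ± 0.046 and the receptor NOTCH4 one of -2.11 ± 0.073, whereas the Notch ligand JAG1 (1.06 ± 0.047) and HEY2 rose. Against all other genes the list was lower (camera adjusted p = 5.6e-05, and adjusted p = 0.445 with an estimated correlation). Of 18 genes of tip cells and VEGF signalling, 1 rose and 17 fell (also adjusted over the list alone), with a median of -1.23 (camera adjusted p = 4.2e-08, and adjusted p = 0.442 with an estimated correlation). Examples were the growth factor PDGFB (-2.83 ± 0.062), RGCC (-2.12 ± 0.070), the main VEGF receptor KDR (-2.004 ± 0.058) and the semaphorin receptor PLXND1 (-1.55 ± 0.053). The member that rose was the lymphatic growth factor VEGFC (0.30 ± 0.076), which lost its call without siCon 1 (adjusted p = 0.0557; 5.4e-06 to 1.00 over its alternatives). EFNB2, KDR and PLXND1 carry the 8-base word in their 3′ UTR. The leading word occurs in 1 of 13 lower arterial genes and in 3 of 17 lower angiogenic genes.

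Markers of endothelial identity fell on balance. Of 24 pan-endothelial markers, 3 rose, 19 fell and 2 did not pass (also adjusted over the list alone), with a median log2 fold change of -0.90 (camera adjusted p = 1.0e-05, and adjusted p = 0.462 with an estimated correlation). The sialomucin EMCN fell from 77.1 ± 2.60 to 16.6 ± 0.859 CPM and VWF from 2353 ± 30.8 to 573 ± 46.7 CPM, with KDR and CDH5 also among the 4 members of smallest p. NOS3, the angiopoietin receptor TEK (0.34 ± 0.045) and the adhesion molecule ICAM2 (0.58 ± 0.048), which shares bases with PRR29 on the other strand, rose, and TIE1 and ESAM did not pass. The NOS3 call was lost without siCon 1 (adjusted p = 0.134). Beside these markers, ACTA2, CNN1 and SMTN of the smooth muscle list (log2 fold changes 1.49, 1.37 and 0.33) and RGS5 of the pericyte list (1.28) rose, and COL1A1, COL1A2 and COL3A1 of the latter (-1.28, -1.44 and -1.72) fell. The leading word occurs in 5 of 19 lower pan-endothelial markers, CDH5 and KDR among them.

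Junction genes were lower as a group, with tight junction members among the exceptions. Of 23 tested, 5 rose, 15 fell and 3 did not pass (also adjusted over the list alone), with a median log2 fold change of -0.48 (camera adjusted p = 0.00768, and adjusted p = 0.442 with an estimated correlation). The plaque proteins PKP4 (-1.68 ± 0.075) and JUP (-1.31 ± 0.052) fell with CDH5 (-1.22 ± 0.046), while the tight junction protein CGN (3.90 ± 0.30) rose, as did OCLN, CTNND1 and PVRL2. The leading word occurs in 5 of 15 lower members, PKP4 and CDH5 among them. With all its carriers left out, the list's median was -0.49 against -0.48 before, and its call was lost (adjusted p = 0.0514) with fewer members tested. With all carriers of the 6-base core left out, the median was -0.24 (adjusted p = 0.629; 7.5e-05 to 0.629 over its alternatives).

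Genes of inflammatory activation were lower. Of 24 tested, 2 rose, 19 fell and 3 did not pass (also adjusted over the list alone), with a median log2 fold change of -0.94 (camera adjusted p = 2.5e-05, and adjusted p = 0.442 with an estimated correlation). SELE, which shares bases with C1orf112 on the other strand, fell from 12.2 ± 0.610 to 0.575 ± 0.175 CPM and VCAM1 from 33.5 ± 0.123 to 4.99 ± 0.676 CPM. CCL2 (-5.08 ± 0.12) and the transcription factor IRF1 (-1.91 ± 0.089) also fell and are among the 5 of 19 lower members that carry the leading word. The members that rose were TNFAIP3, an inhibitor of NF-κB signalling, and CSF3. Of 35 interferon response genes, 2 rose, 23 fell and 10 did not pass (also adjusted over the list alone), with a median of -0.85 (camera adjusted p = 0.00952, and adjusted p = 0.782 with an estimated correlation). XAF1 had a log2 fold change of -2.06 ± 0.21 and the antiviral membrane protein IFITM3 one of -0.89 ± 0.087, and the neighbours DTX3L (-1.75 ± 0.13) and PARP9 (-1.59 ± 0.17), whose products form a complex, overlap by 240 bases on opposite strands. IFI44 and BST2 rose. Without siCon 1 the interferon median was -0.40 and the call was lost (adjusted p = 0.0837), as it was with cameraPR (0.133; 4.4e-05 to 0.782 over its alternatives). The leading word occurs in 5 of 23 lower interferon genes, DTX3L among them.

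Coagulation and flow-responsive genes moved in both directions. Of 18 coagulation and fibrinolysis genes, 7 rose, 9 fell and 2 did not pass (also adjusted over the list alone), with a median log2 fold change of -0.12 (camera adjusted p = 0.460; lower with cameraPR, adjusted p = 0.00365, and 0.00365 to 0.624 over its alternatives). The protease-activated receptor F2RL1 (-2.79 ± 0.055), the protease inhibitor TFPI2 (-1.68 ± 0.046) and the plasminogen-binding annexin ANXA2 (-1.65 ± 0.052) fell, and SERPIND1, the thrombin inhibitor heparin cofactor II, rose (3.32 ± 0.10). SERPIND1 lies within PI4KA on the other strand, and PI4KA also rose (0.68 ± 0.056). Of 9 genes of the shear stress and KLF2/KLF4 programme, 4 rose, 2 fell and 3 did not pass (also adjusted over the list alone), with a median of -0.15, a mean of 0.20 and a test in the higher direction (camera adjusted p = 0.697). KLF2 (2.04 ± 0.083), KLF4 (1.44 ± 0.13), CYP1B1 (1.58 ± 0.27) and NOS3 rose, NOS3 losing its call without siCon 1 (adjusted p = 0.134), and THBD and CYP1A1, a xenobiotic-metabolising enzyme, fell (-2.46 ± 0.16). CYP1B1 rose although its 3′ UTR carries the 8-base word.

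Matrix genes and genes of TGFβ signalling fell on balance. Of 34 extracellular matrix genes, 6 rose, 26 fell and 2 did not pass (7 and 26 adjusted over the list alone), with a median log2 fold change of -0.69 (camera adjusted p = 1.8e-05, and adjusted p = 0.442 with an estimated correlation). The collagen COL12A1 had a value of -3.70 ± 0.14, periostin (POSTN) one of -3.54 ± 0.069, THBS1 one of -3.35 ± 0.053 and the laminin chain LAMA4 one of -1.25 ± 0.046. Of 25 genes of TGFβ response and endothelial-to-mesenchymal transition, 5 rose, 15 fell and 5 did not pass (also adjusted over the list alone), with a median of -0.55 (camera adjusted p = 0.00952, and adjusted p = 0.442 with an estimated correlation). BMP4, a ligand of the family (-3.56 ± 0.085), the secreted TGFBI (-3.12 ± 0.057) and the receptor TGFBR2 (-2.27 ± 0.045) fell, and smooth muscle actin ACTA2 rose from 19.4 ± 0.334 to 54.8 ± 1.48 CPM, as did CNN1, ZEB2, ID1 and ID2. ACTA2 overlaps FAS on the other strand, and FAS rose too (0.86 ± 0.082). The leading word occurs in 6 of 26 lower matrix genes, COL12A1 among them, and in 4 of 15 lower TGFβ genes, TGFBR2 among them. With all carriers of the 6-base core left out, and fewer members tested, the median of the TGFβ list was -0.39 and its call was lost (adjusted p = 0.146; 7.8e-05 to 0.442 over its alternatives).

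YAP/TAZ target genes went both ways. Of 21 tested, 9 rose, 9 fell and 3 did not pass (9 and 10 adjusted over the list alone), with a median log2 fold change of -0.04 (camera adjusted p = 0.532; lower with cameraPR, adjusted p = 0.0281, and 0.0281 to 0.968 over its alternatives). CTGF (-2.91 ± 0.051), ARHGEF17 (-1.74 ± 0.055) and CYR61 (-1.34 ± 0.052) fell, and the receptor tyrosine kinase AXL rose (0.95 ± 0.045). The leading word occurs in 4 of 9 lower targets, CTGF, ARHGEF17 and CYR61 among them, and in 3 of 9 higher ones. Of 25 Hippo pathway components, 10 rose, 10 fell and 5 did not pass (11 and 11 adjusted over the list alone), with a median of -0.07, a mean of 0.04 and a test in the higher direction (camera adjusted p = 0.948). The kinases LATS2 (0.60 ± 0.045), STK4 (0.65 ± 0.051) and MAP4K4 (0.68 ± 0.053) rose, MAP4K4 although its 3′ UTR carries the leading word. The scaffold protein AJUBA, which carries the 8-base word, fell (-0.99 ± 0.062). Carriers of the leading word were 7 of 10 lower and 2 of 10 higher Hippo components.

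**Figure D4:**
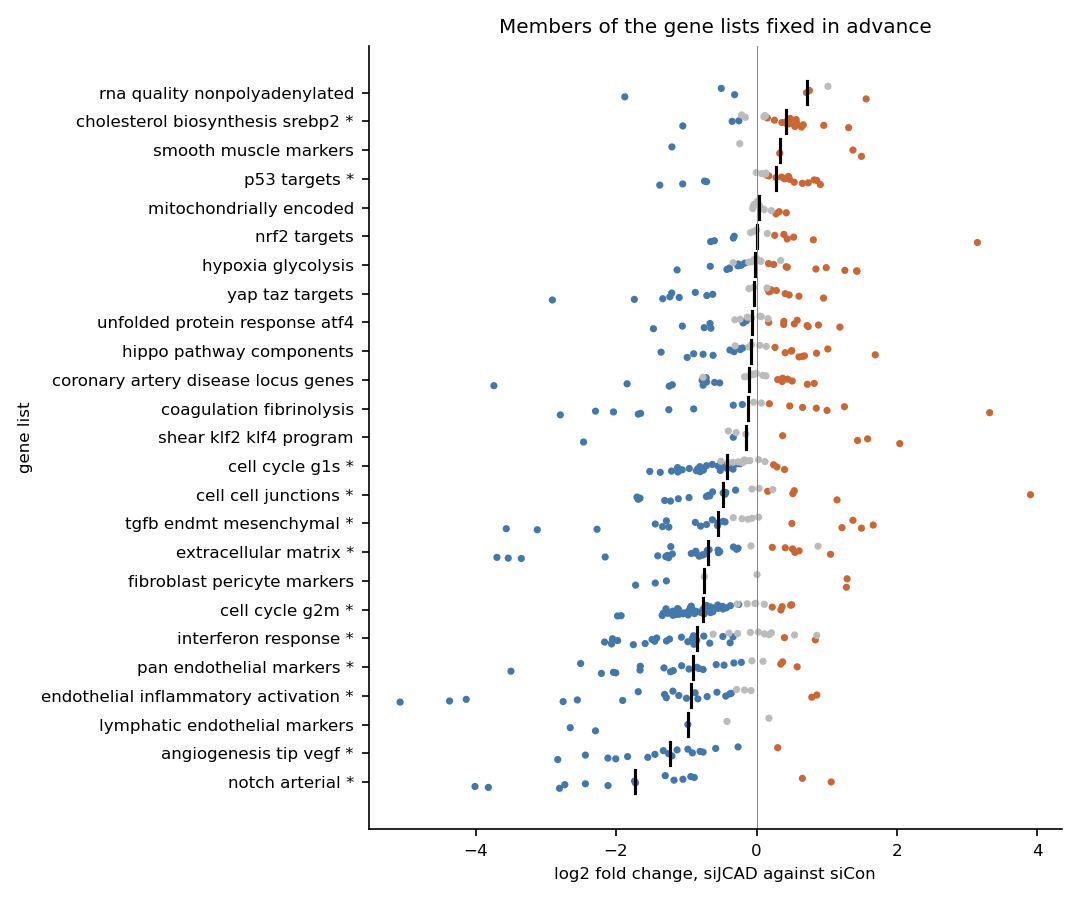
Each point is a tested member of a gene list fixed in advance, at its log2 fold change of siJCAD against siCon; orange members were higher, blue lower and grey not past the test (edgeR, adjusted p below 0.05), black bars are medians and lists with an asterisk passed camera at its preset correlation. Medians run from -1.72 for the arterial list to 0.71 for the transcripts without a poly-A tail or kept in the nucleus, and lists with fewer than 5 tested members and 1 further list are not drawn.

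Proliferation genes were lower and p53 targets were higher. Of 54 genes of G2 and mitosis, 5 rose, 44 fell and 5 did not pass (6 and 45 adjusted over the list alone), with a median log2 fold change of -0.76 (camera adjusted p = 1.9e-07, and adjusted p = 0.442 with an estimated correlation). The heterochromatin protein CBX5 (-1.98 ± 0.069), the kinetochore motor CENPE (-1.93 ± 0.12), the anaphase activator CDC20 (-1.34 ± 0.080) and the mitotic kinase PLK1 (-1.19 ± 0.080) fell. CBX5 and CENPE carry the 8-base word, and the leading word occurs in 6 of 44 lower members. Of 41 genes of G1 and S phase, 3 rose, 27 fell and 11 did not pass (3 and 29 adjusted over the list alone), with a median of -0.42 (camera adjusted p = 2.7e-04, and adjusted p = 0.442 with an estimated correlation). CDCA7 (-1.52 ± 0.15), thymidylate synthase TYMS (-1.37 ± 0.073), the ribonucleotide reductase subunit RRM2 (-1.12 ± 0.065) and the histone chaperone NASP (-0.80 ± 0.052) fell. Of 23 p53 targets, 15 rose, 4 fell and 4 did not pass (also adjusted over the list alone), with a median of 0.28 (camera adjusted p = 0.0232, and adjusted p = 0.591 with an estimated correlation). CDKN1A (0.91 ± 0.049) and the pro-apoptotic BAX (0.65 ± 0.050) rose, while the death receptor TNFRSF10B (-1.38 ± 0.044) and the DNA repair protein XPC (-1.05 ± 0.057), which both carry the leading word, fell, as did MDM2 and CCNG1. Without siCon 1 the p53 list lost its call (adjusted p = 0.0532), as it did with the replicate number as a block (0.0683) and with cameraPR (0.159; 0.00197 to 0.591 over its alternatives).

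Cholesterol synthesis genes were higher. Of 23 tested, 15 rose, 3 fell and 5 did not pass (also adjusted over the list alone), with a median log2 fold change of 0.42 (camera adjusted p = 0.00952, and adjusted p = 0.442 with an estimated correlation). The sterol oxidase MSMO1 rose from 57.6 ± 2.24 to 143 ± 17.1 CPM, and the reductase DHCR7 (0.64 ± 0.050) and the transcription factor SREBF2 (0.55 ± 0.045) rose, whereas SC5D, a desaturase whose 3′ UTR carries the leading word, fell (-1.05 ± 0.099), as did SQLE and FDPS. With all carriers of the 6-base core left out, and fewer members tested, the median was 0.23 and the call was lost (adjusted p = 0.150; 0.00132 to 0.442 over its alternatives).

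Stress-response lists went both ways. Of 15 NRF2 targets, 6 rose, 4 fell and 5 did not pass (also adjusted over the list alone), with a median log2 fold change of 0.00 (camera adjusted p = 0.673). HMOX1 (3.15 ± 0.064) and OSGIN1 (0.81 ± 0.073) rose, and the ferritin chain FTL (-0.65 ± 0.046) and the quinone reductase NQO1 (-0.60 ± 0.044) fell. Of 29 hypoxia and glycolysis genes, 9 rose, 10 fell and 10 did not pass (also adjusted over the list alone), with a median of -0.02, a mean of 0.10 and a test in the higher direction (camera adjusted p = 0.956). NDRG1 (1.43 ± 0.052), hexokinase HK2 (1.43 ± 0.061) and enolase ENO2 (1.26 ± 0.067) rose and the vasodilator peptide ADM fell (-1.13 ± 0.079). Of 25 genes of the unfolded protein response and ATF4, 9 rose, 8 fell and 8 did not pass (also adjusted over the list alone), with a median of -0.07 (camera adjusted p = 0.992). Asparagine synthetase ASNS rose (1.19 ± 0.088), while EDEM1 (-1.47 ± 0.046), the transcription factor ATF4 (-0.74 ± 0.054) and the chaperone HSP90B1 (-0.65 ± 0.047) fell.

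Genes at other loci associated with coronary artery disease moved in both directions. Of 28 tested, 8 rose, 11 fell and 9 did not pass (also adjusted over the list alone), with a median log2 fold change of -0.10 (camera adjusted p = 0.414). The chemokine CXCL12 fell from 12.8 ± 0.949 to 0.947 ± 0.223 CPM, and SWAP70 (-1.24 ± 0.048), the basement membrane collagen COL4A1 (-1.20 ± 0.073) and the VEGF receptor FLT1 (-0.76 ± 0.042) fell as well. Of the lower members, 3 of 11 carry the leading word, but none of these 4 does, of which SWAP70 and COL4A1 carry the word shifted by 1 base.

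Markers of other vascular and stromal cells did not move alike. Of 5 lymphatic endothelial markers, 0 rose, 3 fell and 2 did not pass (also adjusted over the list alone), with a median log2 fold change of -0.98 (camera adjusted p = 0.0671). LYVE1 fell from 3.80 ± 0.331 to 0.593 ± 0.0843 CPM and MMRN1, which carries the 8-base word, from 2127 ± 72.2 to 434 ± 43.4 CPM. Without siCon 2 this list passed as lower (adjusted p = 0.0294), as it did with the replicate number as a block (0.0258) and with cameraPR (0.0206; 0.0206 to 0.442 over its alternatives). Of 5 smooth muscle markers, 3 rose, 1 fell and 1 did not pass (also adjusted over the list alone), with a median of 0.33 (camera adjusted p = 0.259). ACTA2 (1.49 ± 0.063), SMTN (0.33 ± 0.057) and CNN1 (1.37 ± 0.27, from 0.948 CPM) rose, and MYH11 fell from 0.576 ± 0.0641 to 0.245 ± 0.0873 CPM, a call lost without siCon 1 (adjusted p = 0.0992), siCon 2 (0.174) or siJCAD 2 (0.0774), with a range of 0.0278 to 0.249 over its alternatives. Of 7 fibroblast and pericyte markers, 2 rose, 3 fell and 2 did not pass (also adjusted over the list alone), with a median of -0.74 (camera adjusted p = 0.697). The collagens COL3A1 (-1.72 ± 0.16), COL1A2 (-1.44 ± 0.16) and COL1A1 (-1.28 ± 0.25), the last carrying the 8-base word, fell, CSPG4 rose, and RGS5 rose from 264 ± 17.2 to 642 ± 35.7 CPM. RGS5 overlaps NUF2 on the other strand, which fell (-0.71 ± 0.16).

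Epithelial and leukocyte markers were mostly scarce. Of 4 epithelial markers, 3 rose and 1 fell (also adjusted over the list alone). The keratin KRT7 fell from 199.9 ± 2.39 to 58.5 ± 1.87 CPM, and KRT19 and MUC1 rose from 2.47 ± 0.0177 to 4.19 ± 0.601 CPM and from 1.39 ± 0.213 to 3.11 ± 0.533 CPM. EPCAM, at 0.129 CPM in siCon and 0.489 CPM in siJCAD, was higher by 1.93 ± 0.73. Its value was 0.91 without siCon 1, where its call was lost, and 6.41 without siCon 2. The latter is not a measured fold, since siCon 1, the only control library left, held 0 counts of EPCAM. Its call was also lost without siJCAD 2 (adjusted p = 0.0667), with DESeq2 (0.123) and with no filter on low counts (0.0516). Of 2 leukocyte markers with enough counts, LAPTM5 fell from 224 ± 2.80 to 170.0 ± 12.3 CPM and FCER1G, at 0.426 and 0.637 CPM, did not pass, also adjusted over the list alone.

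Neither list of transcripts fixed as signs of RNA quality was called with all libraries, though single members differed. Of 13 mitochondrially encoded transcripts, 3 rose, 0 fell and 10 did not pass (2 and 0 adjusted over the list alone), with a median log2 fold change of 0.04 (camera adjusted p = 0.425). MT-ND3, at 0.28 ± 0.069, and MT-ND6, at 0.42 ± 0.12, rose with MT-ND5. Without siCon 1 MT-ND3 stood at 0.16 (adjusted p = 0.0957; 4.1e-08 to 1.00 over its alternatives) and MT-ND6 at 0.20 (adjusted p = 0.0621; 2.3e-19 to 0.991 over its alternatives), while without siCon 2 MT-ND6 stood at 0.69 and the list passed as higher with a median of 0.28 (adjusted p = 8.7e-04; 8.7e-04 to 0.908 over its alternatives). Mitochondrial counts made up 2.52% of siCon 1, 3.38% of siCon 2 and 3.17% to 3.50% of the siJCAD libraries. Of 7 transcripts that lack a poly-A tail or stay in the nucleus, 3 rose, 3 fell and 1 did not pass (also adjusted over the list alone), with a median of 0.71 (camera adjusted p = 0.697). The nuclear RNA NEAT1 had a log2 fold change of 1.56 ± 0.10. RN7SK, at 0.71 ± 0.21, lost its call without siCon 1 (adjusted p = 0.113; 0.00422 to 0.195 over its alternatives), as did the histone gene HIST1H2BD, at -1.88 ± 0.46 (adjusted p = 0.0617; 3.6e-06 to 0.0617 over its alternatives). MALAT1, at -0.31 ± 0.083, stood at -0.18 without siCon 2 (adjusted p = 0.131; 1.3e-10 to 1.00 over its alternatives).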

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

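The settings that leave out genes by their 3′ UTR word, and all alternatives of the gene families, were chosen only after the results were seen. No gene called in both had opposite directions in any alternative. Of the alternatives of the named genes, 2173 kept direction and side of the threshold, 39 lost the call, 2 gained one and 5 reversed, and for the lists, fry set aside, the numbers were 337, 21, 11 and 15. Calls were 3649 higher and 3916 lower with DESeq2, 4666 and 4637 with limma-trend, 4956 and 4400 with upper-quartile factors and 4691 and 4663 with no filter. Testing against a log2 change of 0.5 (glmTreat) left 1426 and 2231, since smaller changes no longer count. With carriers of the 6-base core left out, 2486 and 2539 were called, fewer genes being tested.

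Leaving out 1 library in turn gave 3492 (without siCon 1) to 4750 (without siJCAD 3) higher and 3878 to 4849 lower genes, 9 to 12 lists lower, 1 (without siCon 1) to 3 lists higher, and KIAA1462 at -2.80 to -2.76. A lone siCon library is assumed to vary like the siJCAD ones. Reversed values over these settings were F3 -0.12 to 0.042, WWTR1 -0.014 to 0.085 and YAP1 -0.22 to 0.016. For some lists and families the direction by test turned in some of these settings, though their medians need not change sign. Medians of these lists were -0.11 to 0.016 for Hippo, -0.048 to -0.016 for hypoxia, -0.18 to 0.28 for mitochondrial and -0.085 to 0.0081 for unfolded protein response genes. Medians of these families were 0.013 to 0.10 for cytosolic ribosomal proteins and 0.017 to 0.21 for integrins. The cause was not tested.

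Lists higher numbered 0 (and 0 lower) with an estimated correlation, 6 with fry, 1 with cameraPR, 1 with the replicate block and 1 with carriers of the core left out. The direction by test also turned for the unfolded protein response list at medians of -0.071 (DESeq2 factors), -0.029 (upper quartile), -0.046 (no filter), -0.065 (strict filter) and -0.064 (block), for fibroblast markers at -0.74 (cameraPR), for hypoxia at -0.12 and shear at -0.26 (leading word left out), and for hypoxia at -0.13 and YAP/TAZ targets at 0.14 (core left out). Cytosolic ribosomal proteins stood at 0.0032 (word left out) and -0.032 (core left out). The cause was not tested.

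Replicate numbers do not pair the samples: correlations of deviations for equal numbers were -0.0222 and 0.00899. With the number as a block, 4862 genes were higher and 4970 lower, and WWTR1 stood at -0.018; the calls that changed included YAP1 and the lymphatic list (gained), and the p53 list and the kinesins (lost).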

Other observations

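The gene families, the tests of library scaling, of a lower endothelial share and of the control siRNA's seed, and the genes named only here were chosen only after results were seen. Subunits of the vacuolar proton pump, which acidifies lysosomes, were higher: of 21 tested, 15 rose, 1 fell and 5 did not pass (also adjusted over the list alone), with a median log2 fold change of 0.54 (camera adjusted p = 3.1e-05, and adjusted p = 0.366 with an estimated correlation). Besides ATP6V0D2, members such as ATP6V0A1 (1.04 ± 0.053), ATP6V0E1 (0.94 ± 0.045) and ATP6V0D1 (0.86 ± 0.047) rose, and ATP6V0A2 fell. NDUF genes, which mostly encode subunits of mitochondrial complex I, were higher by less: of 36, 21 rose, 2 fell and 13 did not pass (also adjusted over the list alone), with a median of 0.21 (camera adjusted p = 0.00768, and adjusted p = 0.582 with an estimated correlation), NDUFS1 and NDUFB10 being those that fell. Of 34 kinesin motors, 6 rose, 18 fell and 10 did not pass (7 and 20 adjusted over the list alone), with a median of -0.47 (camera adjusted p = 0.0481, and adjusted p = 0.366 with an estimated correlation). The kinesin call was lost without siCon 1 (adjusted p = 0.0623) or siJCAD 1 (0.0651), with the replicate number as a block (0.135), with libraries thinned to the smallest (0.0520) and with carriers of the leading word left out (0.102; 0.0274 to 0.366 over its alternatives).

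Among proteasome genes, 5 that interferon induces were picked after their falls were seen and were not tested as a group. Log2 fold changes were -2.78 ± 0.19 for PSMB9, -1.90 ± 0.18 for PSMB10 and -0.80 ± 0.11 for PSMB8, and -1.66 ± 0.082 and -1.07 ± 0.070 for the activator subunits PSME2 and PSME1. PSMB9 carries the 8-base word in its 3′ UTR and shares bases with PSMB8 and TAP1 on the other strand. Of all 41 proteasome genes, 18 rose, 9 fell and 14 did not pass (19 and 9 adjusted over the list alone), with a median of 0.11 and a mean of -0.07 (camera adjusted p = 0.194). Among families without a call, 6 HLA class I genes had a median of 0.25 (adjusted p = 0.188), 76 mitochondrial ribosomal proteins one of 0.11 (0.188), 78 cytosolic ones one of 0.05 with a mean of -0.013 and a test in the higher direction (0.596), 19 semaphorins one of 0.31 (0.258) and 20 integrins one of 0.24 with a mean of -0.22 (0.816). Without siJCAD 3 the cytosolic ribosomal list passed as higher (adjusted p = 0.0328; 0.0328 to 0.976 over its alternatives). With no filter on low counts, mitochondrial ribosomal proteins (adjusted p = 0.0274) and the proteasome genes (0.0420) passed as higher, and with carriers of the 6-base core left out the integrins did (0.0227).

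The first pattern weighed is the word GGAAATG in the 3′ UTRs of lower genes, for which a candidate explanation is the seed of the siRNA against JCAD, pairing like a microRNA. The word's t of -18.0 and the rank of words that overlap it restate the pattern and do not point to an siRNA in particular. The JCAD transcript holds the leading word GGAAATG, but 38.0% of all 7-base words occur in it. It also holds the joined word GGAAATGA, in coding exon 3 of 4 (chromosome 10, 30027483 to 30027490, minus strand), as the end of GGAAACAGCCCGGAAATGA. The share of all 8-base words that occur in the transcript was not computed. This seed thus cannot be told apart from other readers of the word. GGAAATG lies at percentile 100 of 139 words of the same letters, but this was fixed in advance, since it was picked as the strongest of all words. The gap in t was not fixed. The strongest other word of these letters, GAAATGG, which also holds the core, had a t of -5.38 against -18.0. Base composition alone, which these words share, is argued against by that gap. The siRNA sequence was not used here, a microRNA with the same seed that differs between the groups would leave the same trace, and neither was tested.

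The second pattern is that 63.04% of tested genes differed. Library scaling as the whole cause is argued against by at least 1420 genes called in each direction by glmTreat under each of 3 scalings. That test, against a log2 change of 0.5, called only 24.9% of tested genes with TMM factors. For smaller differences scaling stays open, since 4486 called genes differed by less than 1.5-fold. Upper-quartile factors gave 4956 higher and 4400 lower genes, where TMM factors gave 4568 and 4692. Transcript length and GC as the cause are argued against by the 0.252% of variance they explain. Direct lowering through 3′ UTR sites of the leading word as the whole cause of the lower genes is argued against by the 68.5% of them that lack it there. Other sites are not excluded, since the word in the 5′ and coding parts of 2796 genes went with a log2 difference of -0.21 ± 0.020. The 2068 genes with only the 6-base core in the 3′ UTR had a median of 0.06, with 30.6% lower. Those without the core had 0.07 and 27.5%. The core was lacking there in 42.8% of the lower genes, against 6686 of all 12713 searched. In the whole transcript 23.4% of the lower genes lacked it, with no share over all genes to set beside this. What follows in other genes from lowering of carriers is open too. Seed sites of the control siRNA cannot be told apart from none: the strongest positive t of any word was 4.35, below the 5.33 of the strongest permutation, but weak sites would not pass. Loss of JCAD and effects of the siRNA on other genes both may contribute, since the siJCAD samples differ from siCon in both, and the design named only JCAD.

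The third pattern is the fall of pan-endothelial markers. A lower share of endothelial cells in the siJCAD cultures, as the whole cause, would lower these markers alike. It is argued against by 3 abundant markers that rose, NOS3, TEK and ICAM2, while 19 markers fell. The rule was written after these rises were seen, and a lower share beside changes within the cells is not excluded. The NOS3 call was lost without siCon 1, siCon 2, siJCAD 1 or siJCAD 2 (adjusted p 8.2e-24 to 1.00 over its alternatives). TEK and ICAM2 did not pass against a log2 change of 0.5 (glmTreat, adjusted p = 0.0684 for ICAM2). Stromal markers do not decide. COL1A2 fell (-1.44 ± 0.16) and ACTA2 rose (1.49 ± 0.063), but they mark different cells, and ACTA2 overlaps FAS, which also rose. Direct lowering through 3′ UTR sites of the word as the cause for the whole list is argued against by the 26.3% of its lower members that carry the word, which leaves it open for those, CDH5 and KDR among them, and through weaker or coding sites for others. A change of endothelial state after JCAD loss, the difference the design names, may explain the fall and stays open as a hypothesis, untested apart from effects of the siRNA on other genes. Another siRNA against JCAD with a different seed, or a rescue with a resistant JCAD, would tell these apart and was not analysed here.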
